A study of Homo sapiens with 12 samples.

How the data were processed

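Total RNA from A375 and SKMel28 melanoma cells, grown with 10% FBS, was poly(A)-selected and sequenced, per the labels' protocols. Each line was present as vemurafenib-resistant and as sensitive cells, with 3 libraries per group and 12 in all. The deposited values are raw counts of reads per gene symbol for 26499 genes, in 1 file per library, each ending in 5 summary lines in the style of htseq-count. The submitters' processing notes name HISAT2, StringTie and the genome build GRCh38.p12, while the deposited files' own names point to alignment with STAR of untrimmed reads and unstranded counting on hg38 genes with the mitochondrial genome. Which aligner made the deposited counts is therefore not settled, and the values were used as counts because they are whole numbers with htseq-count's summary lines. Because counting was unstranded by those names, reads of overlapping and antisense genes cannot be told apart.

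Reads assigned to genes ranged from 28496518 to 37721363 per library, and 15.1% to 19.5% of counted reads were not assigned. Of counted reads, 11.7% to 13.5% met no gene, 1.14% to 1.39% met more than 1 gene and 2.09% to 5.03% aligned to more than 1 place. Floors for genes without reads were set at 3 reads over a group and cover counting error only, since reads without molecular identifiers are not independent molecules. Chi-square over degrees of freedom between replicates ran from 2.81 to 7.45, so no library was a copy of another. Residuals of the same number in resistant and sensitive cells had correlations from -0.0243 to -0.00399 in A375, where replicate numbers did not pair libraries. In SKMel28 a shared effect of replicate number cannot be excluded. There the same-number correlations were 0.205 for number 1, -0.00986 for number 2 and 0.153 for number 3. Resistant 1 with sensitive 3 was at -0.170 and resistant 3 with sensitive 1 at -0.195.

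Counts were filtered with filterByExpr, which left 15506 genes, scaled by TMM and fitted in 1 model with 4 group means and 8 residual degrees of freedom (edgeR 4.0.16, robust quasi-likelihood, R 4.3.3). The biological coefficient of variation was 4.20%. Contrasts were resistant minus sensitive within A375, the same within SKMel28, and the first minus the second as the difference between lines. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, in a two-sided test. CPM values are counts scaled to the TMM-adjusted library size, given as mean ± SD over 3 libraries, and log2 fold changes are fitted values with standard errors.

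Gene lists, 33 in number with 777 different genes, covered signalling, melanoma cell states, stress and metabolism, and markers of other cell types. Some genes belong to more than 1 list, so the lists are not independent of one another. They were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over lists with at least 5 tested members. Camera with an estimated correlation and fry stood beside it. Genes were named by a rule with 4 parts. The first took, per line, the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between groups, passing over unnamed loci and small or antisense RNAs. The second took 18 core genes of the IGF axis, the MAPK pathway and melanoma cell states. The third took up to 3 called members of smallest adjusted p, or members already named, for each list described. The fourth took, among called genes with a mean of at least 10 CPM in the higher group of each line, the 5 that rose and the 5 that fell most in both lines and 4 that went opposite ways in each sense. It ranked them by the smaller absolute log2 fold change and passed over the same kinds of symbols. Of the genes the rule names, 1 is not reported here. Genes outside this rule are said to be chosen after their values were seen.

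Gene positions, GC content and transcript lengths came from GENCODE release 29 (GRCh38). Of the symbols, 23839 matched directly, 80 matched through another symbol and 2580 did not match; 14561 tested genes (93.9%) had a position. Arm medians used genes at 2 CPM or more on arms with at least 20 such genes, with intervals from 1000 bootstrap resamples, and an arm was called shifted beyond 0.25 on the log2 scale. This step was added after the data had been examined.

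The steps were tested on simulated counts drawn from the real means and library sizes, in which 196 of 15330 genes were changed in the A375 comparison. The edgeR test recovered 33 of 48 genes changed 1.25-fold, 37 of 50 changed 1.5-fold, 43 of 50 changed 2-fold and 44 of 48 changed 4-fold, with 7 false calls. The simulated difference between lines was recovered for 132 of 196 genes, and DESeq2 recovered 153 of 196 with 5 false calls in A375. Each set test found 5 of 5 changed sets. Genes were simulated independently, so this does not test lists whose genes vary together, such as mitochondrially encoded genes (estimated correlation 0.623). Far fewer genes were changed than were called in the real data.

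Alternatives tried were DESeq2 size factors in place of TMM, the DESeq2 1.42.0 Wald test, no filter and a stricter filter, each line fitted alone, replicate number as a block, a test against a fold of 1.5 (edgeR glmTreat), and leaving out each library in turn. Scaling by library size alone and leaving out the genes of shifted chromosome arms were added after the data had been examined. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.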

Results

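Poly(A)-selected RNA was sequenced from A375 and SKMel28, established human melanoma cell lines, each as a vemurafenib-resistant derivative and as its sensitive counterpart. Each of the 4 groups held 3 libraries. Vemurafenib inhibits the mutant BRAF kinase that drives many melanomas. The series was set up to ask what part the IGF1 pathway plays in resistance to drugs against BRAF and MEK. Resistant cells were kept in 1 µmol/L vemurafenib and no drug is named for the sensitive cells, so each comparison covers acquired resistance and the presence of the drug together. Reads assigned to genes numbered 33468231, 31338296 and 30446340 in the resistant A375 libraries and 37721363, 31144821 and 28496518 in the sensitive ones. In SKMel28 they numbered 35069098, 34058727 and 37148091 in the resistant libraries and 31242802, 31382409 and 32547031 in the sensitive ones. At these depths 1 CPM stood for at least 28 reads. Correlations of log2 CPM ran from 0.991 to 0.995 within a group, from 0.940 to 0.962 between the groups of a line and from 0.752 to 0.791 between lines. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

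The first comparison asked how resistant A375 cells differ from sensitive ones. Resistant A375 cells had lost nearly all transcripts of SOX10, the transcription factor of the neural crest and melanocyte lineage, which went from 325 ± 6.0 CPM (SD, n = 3) to 0.138 ± 0.0487 CPM (log2 fold change -11.18 ± 0.09 SE, edgeR adjusted p = 4.63e-51). Other genes of the neural crest fell with it: SOX5 from 47.2 to 0.226 CPM (-7.69 ± 0.14), the cadherin gene CDH19 from 15.4 to 0.0392 CPM (-8.49 ± 0.21), FOXD3 (-4.88), NES, which encodes nestin (-2.29), and L1CAM (-1.0). The gel-forming mucin gene MUC5B (30.1 to 0.0571 CPM) and the glutathione transferase gene GSTM3 (20.6 to 0.0696 CPM) were among the 6 largest falls. So was GSTM1, with no read left in the resistant libraries and an expression at least 594-fold lower, taking 3 reads over the group as the floor. GSTM1 and GSTM3 belong to a family of similar genes, so their counts are uncertain. The largest rises were of EPB41L3, a membrane skeleton linker (0.0761 to 30.1 CPM, 8.53 ± 0.14), and STC1, the secreted glycoprotein stanniocalcin-1 (11.6 to 290.1 CPM, 4.65 ± 0.06). Other large rises were of the lipid transporter gene ABCA3 (4.35), the caveolar coat gene SDPR (4.03), the G-protein regulator gene RGS4 (3.82) and LOXL1, a cross-linking enzyme of elastic fibres (3.68).

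Of 15506 genes tested, 7959 passed an edgeR adjusted p of 0.05 in A375, 3882 higher and 4077 lower in resistant cells; 629 of the rises and 999 of the falls were at least 2-fold. Which direction held more called genes in A375 turned under other settings, with 4440 higher and 3639 lower with DESeq2 size factors, 4351 and 3703 with scaling by library size, 4357 and 3561 by DESeq2 and 4398 and 3778 with no filter. Rises were also more numerous without the genes of shifted arms (3785 and 3027) and without resistant replicate 1 (54.0% of calls), 2 (54.5%) or 3 (54.9%).

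Of 33 gene lists chosen before the data were examined, 10 were called in A375 by camera with a preset correlation of 0.01. The highest other split of the same libraries, 3 against 3, called 5. Targets of p53 rose, 16 of the 21 tested (median log2 fold change 0.53, adjusted p = 8.23e-06); when adjusted over the list alone 16 rose and 1 fell. Among them were CDKN1A, which encodes the cell cycle inhibitor p21 (180 to 365 CPM, 1.02 ± 0.04 SE), the death receptor gene FAS (1.11 ± 0.08) and RRM2B, a ribonucleotide reductase subunit (0.79 ± 0.05). The neural crest stem list fell, 12 of 16 down and 1 up both over all genes and adjusted over the list alone (median -0.92, adjusted p = 1.50e-05). DNA replication and G1-S genes fell, 20 of 30 down and 1 up (median -0.18, adjusted p = 1.21e-04), or 22 down and 1 up adjusted over the list alone, with E2F2 (-1.39), E2F1 (-0.75) and PCNA (-0.57) leading. With an estimated correlation these 3 lists kept their calls, at adjusted p = 0.0158, 0.0294 and 0.0294.

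Another 7 lists were called in A375 with the preset correlation alone. Lysosome and autophagy genes rose, 18 of 30 up and 6 down (median 0.22, adjusted p = 0.0111, and adjusted p = 0.199 with an estimated correlation). Called members included SQSTM1 (0.66), CTSB (0.68) and LAMP2 (0.76). Immediate early genes rose, 10 of 15 up and 2 down (median 0.41, adjusted p = 0.0184, and adjusted p = 0.199 with an estimated correlation). Called members included EGR1 (1.13), JUN (0.55) and IER2 (0.41). Genes of the ERK transcriptional output rose, 16 of 25 up and 8 down (median 0.25, adjusted p = 0.0218, and adjusted p = 0.278 with an estimated correlation). HMGA2 (0.93), the ERK phosphatase gene DUSP6 (181 to 309 CPM, 0.77 ± 0.04), FOSL1 (0.59) and CCND1, which encodes cyclin D1 (0.19), rose. SPRY4, a feedback inhibitor, fell (-0.45). Inflammatory and NF-kB genes rose, 13 of 24 up and 4 down (median 0.36, adjusted p = 0.0294, and adjusted p = 0.199 with an estimated correlation). Among them were IL1B (1.10), CXCL8 (1.06) and TNFAIP2 (0.67). Cholesterol synthesis genes fell, 15 of 24 down and 3 up (median -0.16, adjusted p = 0.0218, and adjusted p = 0.122 with an estimated correlation). Among them were INSIG1 (-0.82) and DHCR7 (-0.59). Nuclear genes of oxidative phosphorylation rose, 20 of 33 up and 3 down (median 0.14, adjusted p = 0.0184, and adjusted p = 0.447 with an estimated correlation). Among them were UQCRFS1 (0.34), NDUFB8 (0.29) and COX7B (0.25). Mitochondrially encoded genes rose, 8 of 13 up and 1 down (median 0.16, adjusted p = 0.0322, and adjusted p = 0.544 with an estimated correlation). Among them were MT-CYB (0.40), MT-CO2 (0.35) and MT-CO1 (0.24). The mitochondrial share of gene reads was 2.20% ± 0.0859 in resistant and 1.92% ± 0.0698 in sensitive cells (SD, n = 3). Adjusted over the list alone, the counts of these lists were the same except for immediate early genes (11 up), the ERK output (17 up), nuclear oxidative phosphorylation (22 up) and mitochondrially encoded genes (9 up). The mitochondrial list lost its call without resistant replicate 2 (adjusted p = 0.0586) or sensitive replicate 3 (adjusted p = 0.097) and with A375 fitted alone (adjusted p = 0.0655). With replicate number as a block it lost its call too (adjusted p = 0.0533), as did the ERK output (adjusted p = 0.0574).

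The falls in A375 were unevenly spread over the genome. Across 1p (659 genes at 2 CPM or more), 13q (210 genes), 20p (107 genes) and 20q (220 genes) the median log2 fold changes were -0.53, -0.45, -0.46 and -0.36. Their 95% bootstrap intervals were -0.55 to -0.50, -0.49 to -0.39, -0.52 to -0.43 and -0.42 to -0.32. The medians of the other arms ran from -0.06 to 0.20. On these 4 arms, which held 9.47% of the tested genes, lay 1050 of the 4077 falls (25.8%) and 97 of the rises (2.50%). GSTM1, GSTM3, FOXD3 and E2F2 lie on 1p, IRS2 on 13q, PCNA on 20p and E2F1 on 20q. Arms were compared only after the data had been seen. Without the genes of these arms p53 targets, the neural crest list and DNA replication genes kept their calls (adjusted p = 2.50e-06, 1.03e-05 and 8.64e-04), while immediate early genes, inflammatory genes and mitochondrially encoded genes did not (adjusted p = 0.0619, 0.0623 and 0.0619).

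**Figure D1:**
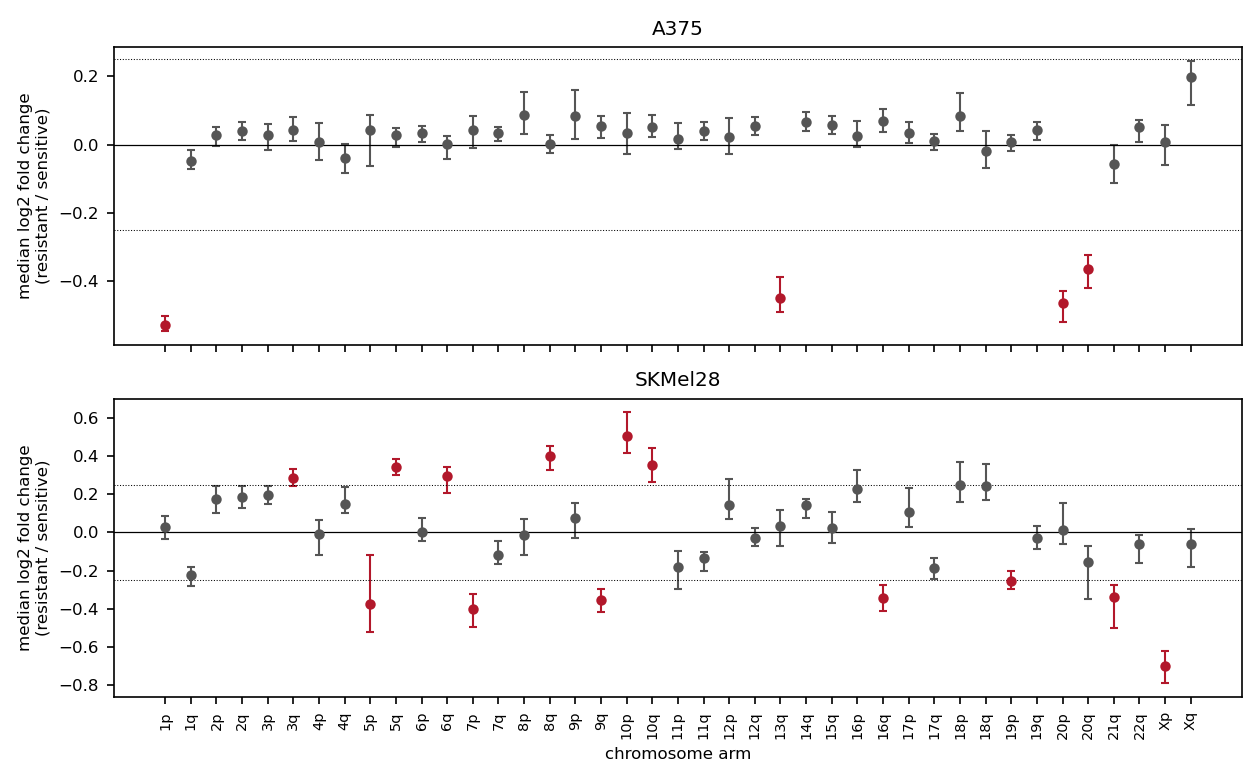
Median log2 fold change (resistant against sensitive) of the genes at 2 CPM or more on each chromosome arm, in A375 (top) and SKMel28 (bottom), with 95% bootstrap intervals over genes; dotted lines mark 0.25 and -0.25, and arms beyond them are red. In A375 only 1p, 13q, 20p and 20q lie beyond the lines, at -0.53, -0.45, -0.46 and -0.36, while 13 arms do so in SKMel28.

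The second comparison put the same question to SKMel28. Resistant SKMel28 cells had lower inflammatory and ERK-dependent transcripts and higher MITF and MLANA transcripts. IL1B, which encodes the cytokine interleukin-1 beta, went from 84.8 ± 4.85 to 0.0922 ± 0.0816 CPM (SD, n = 3; log2 fold change -9.80 ± 0.14 SE, edgeR adjusted p = 9.65e-42). CXCL8 went from 236 to 54.8 CPM (-2.10 ± 0.05). CCND1 went from 2519 ± 42.8 to 769 ± 20.9 CPM (-1.71 ± 0.03, adjusted p = 1.21e-37), SPRY4 from 175 to 75.9 CPM (-1.20 ± 0.04) and DUSP6 from 136 to 76.4 CPM (-0.83 ± 0.04). MITF, the master transcription factor of melanocytes, rose from 508 ± 7.44 to 807 ± 34.8 CPM (0.67 ± 0.03, adjusted p = 3.34e-21). The melanocyte antigen gene MLANA rose from 615 to 907 CPM (0.56 ± 0.04), and SOX10 fell from 722 to 569 CPM (-0.34 ± 0.04).

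The 6 largest falls in SKMel28 were of genes with no read left in the resistant libraries. Taking 3 reads over the group as the floor, expression was at least 3142-fold lower for TFPI2, a serine protease inhibitor (95.6 CPM in sensitive cells). It was at least 1258-fold lower for the phospholipase gene PLA2G16, at least 1009-fold for RGS1 and at least 554-fold for the surface glycoprotein gene CDCP1. It was at least 394-fold lower for SPESP1 and at least 355-fold for SPRR2D, which belongs to a family of near-identical genes and is uncertain. The largest rises were of JAKMIP2 (0.0546 to 34.3 CPM, 9.18 ± 0.25) and CRYAB, which encodes the small heat shock protein alpha-B crystallin (0.299 to 173 CPM, 9.16 ± 0.12). They were followed by the amino acid transporter gene SLC38A8 (7.25 ± 0.30), ANO5 (6.82 ± 0.23), ELFN1 (6.77 ± 0.24) and MAL2 (6.68 ± 0.20). In all, 10854 genes were called, 5301 higher and 5553 lower in resistant cells. Of these, 1343 rises and 1883 falls were at least 2-fold. AXL (-0.23, adjusted p = 0.00258), BRAF (-0.24, adjusted p = 0.0365) and IGFBP2 (-0.18, adjusted p = 0.00192) were called lower although libraries of the 2 groups overlapped. Leaving out resistant replicate 3 ended the calls of AXL (-0.13, adjusted p = 0.0770) and BRAF (-0.12, adjusted p = 0.340), leaving out resistant replicate 1 that of IGFBP2 (-0.11, adjusted p = 0.0506). BRAF also lost its call without resistant replicate 2 (adjusted p = 0.0608), sensitive replicate 2 (adjusted p = 0.130) or sensitive replicate 3 (adjusted p = 0.0667). It did so too by DESeq2 (adjusted p = 0.0533) and in edgeR with no filter (adjusted p = 0.0538).

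In SKMel28, 8 lists were called, and the highest other split of the same libraries, 3 against 3, called 7. The counts that follow were the same adjusted over the list alone. The ERK transcriptional output fell, 24 of 25 down (median -1.28, adjusted p = 4.61e-10), with LIF (-5.54 ± 0.08), the urokinase receptor gene PLAUR (-4.80 ± 0.07) and MAFF (-3.18 ± 0.05) showing the smallest p-values besides the genes above. Inflammatory and NF-kB genes fell, 22 of 24 down (median -1.95, adjusted p = 1.02e-06). These 2 lists kept their calls with an estimated correlation, both at adjusted p = 0.0189. Immediate early genes fell, 13 of 15 down and 2 up (median -0.84, adjusted p = 0.00592, and adjusted p = 0.207 with an estimated correlation). Called members included EGR1 (-2.56), EGR3 (-3.18) and IER2 (-0.91). Genes of the undifferentiated or invasive state fell, 18 of 30 down and 9 up (median -0.45, adjusted p = 0.00988, and adjusted p = 0.207 with an estimated correlation). Among those that fell were TNC, which encodes tenascin-C (1507 to 77.7 CPM, -4.28 ± 0.05), and the nerve growth factor receptor gene NGFR (401 to 22.3 CPM, -4.17 ± 0.05). Glycolysis and hypoxia genes fell, 21 of 30 down and 5 up (median -0.32, adjusted p = 0.00238, and adjusted p = 0.233 with an estimated correlation). Called members included PFKFB4 (-3.24), VEGFA (-1.97) and PGK1 (-1.05). Antigen presentation genes fell, 16 of 24 down and 6 up (median -0.53, adjusted p = 0.0169, and adjusted p = 0.233 with an estimated correlation). Called members included HLA-F (-2.51), HLA-B (-2.23) and HLA-C (-1.29), and reads of these genes are uncertain because the HLA genes resemble one another. Ribosomal protein genes fell, 20 of 30 down and 5 up (median -0.30, adjusted p = 0.00623, and adjusted p = 0.642 with an estimated correlation). Called members included RPLP1 (-1.0), RPS3 (-0.88) and RPS12 (-0.78), which have many processed pseudogenes. Mitochondrially encoded genes rose, 11 of 13 up and 1 down (median 0.60, adjusted p = 0.00152, and adjusted p = 0.479 with an estimated correlation). Called members included MT-CO3 (0.80), MT-CO1 (0.80) and MT-ND4 (0.69). With them the mitochondrial share of gene reads was 6.95% ± 0.163 in resistant against 4.51% ± 0.140 in sensitive cells, and reads aligned to more than 1 place made up 2.26% ± 0.179 against 4.23% ± 0.232 (SD, n = 3). Without the genes of the 13 shifted arms, 3 of these lists lost their call, immediate early genes (adjusted p = 0.129), the undifferentiated list (adjusted p = 0.0641) and ribosomal proteins (adjusted p = 0.0527). In the same setting melanocyte differentiation was called higher (adjusted p = 0.0234, against 0.103 with all genes) and p53 targets lower (adjusted p = 0.0285, against 0.357). With all genes these 2 lists had adjusted p = 0.207 and adjusted p = 0.479 with an estimated correlation.

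**Figure D2:**
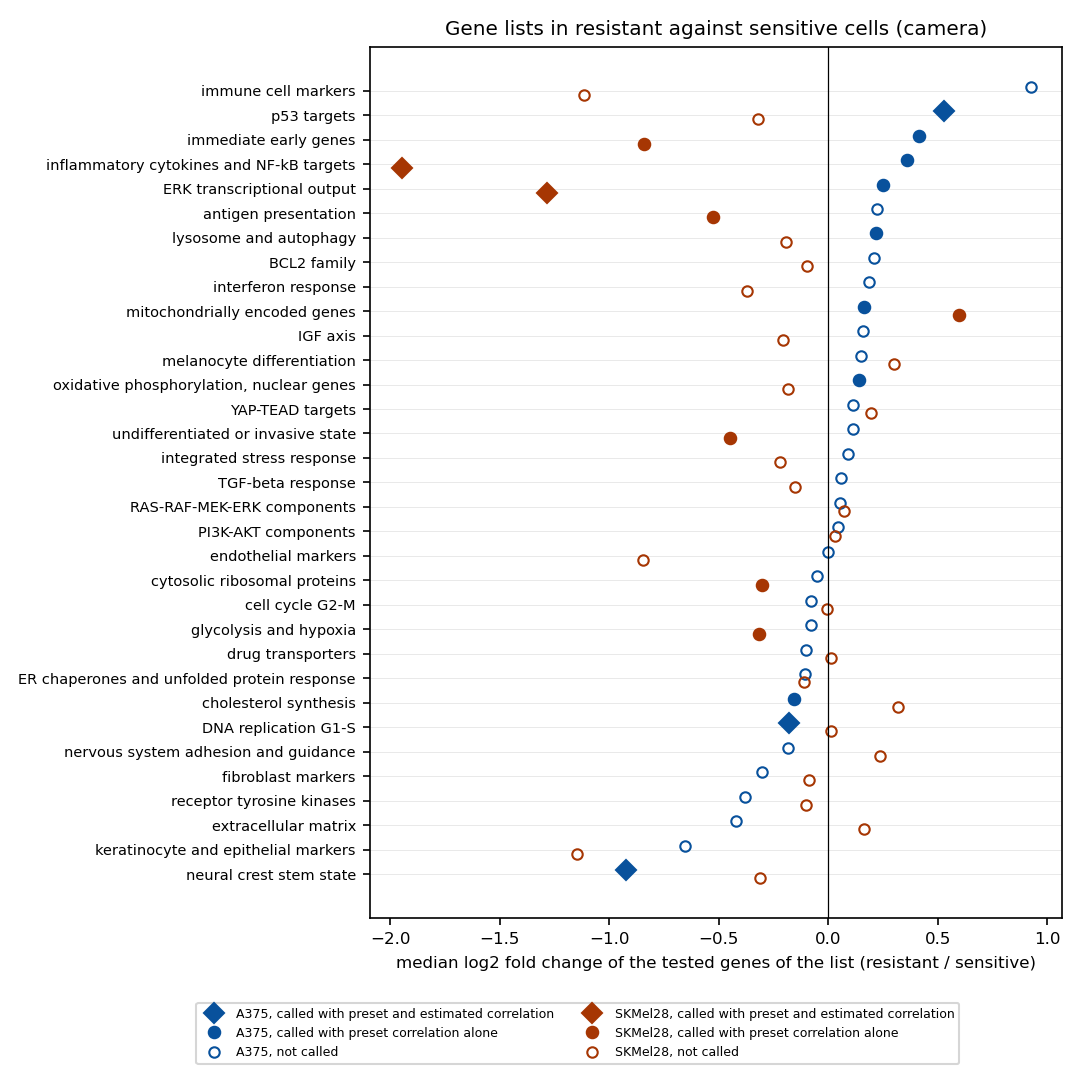
Median log2 fold change (resistant against sensitive, x axis) of the tested genes of each of 33 gene lists (y axis) in A375 (blue) and SKMel28 (brown); diamonds mark lists called by camera with preset and estimated correlation, filled circles those called with the preset correlation alone, open circles the rest. ERK output and inflammatory genes lie at 0.25 and 0.36 in A375 and at -1.28 and -1.95 in SKMel28.

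Called members of the IGF axis, which the series is about, went in different directions within and between the lines. IGF1R, the receptor of IGF1 on chromosome 15 (98648539 to 98964530, GRCh38, plus strand), fell in resistant A375 from 86.1 ± 0.566 to 48.9 ± 2.28 CPM (SD, n = 3; log2 fold change -0.82 ± 0.04 SE, edgeR adjusted p = 2.91e-20). In resistant SKMel28 it rose from 161 ± 7.84 to 274 ± 7.48 CPM (0.77 ± 0.04, adjusted p = 1.83e-21). The 2 changes differed by -1.58 (adjusted p = 3.15e-26). IRS1, the adaptor that passes the receptor's signal on, rose in A375 from 76.2 to 115 CPM (0.59 ± 0.05) and fell in SKMel28 from 39.6 to 11.2 CPM (-1.82 ± 0.06). Its relative IRS2, on 13q, fell in A375 from 148 to 89.0 CPM (-0.73 ± 0.04) and in SKMel28 from 167 to 145 CPM (-0.20 ± 0.04). INSR, the insulin receptor gene, fell in A375 (11.4 to 8.07 CPM, -0.50 ± 0.10); in SKMel28 it was at 14.6 and 13.7 CPM (-0.10 ± 0.10, adjusted p = 0.376), and the difference between lines was -0.40 (adjusted p = 0.0120). IGF1 itself was near the limit of detection: 2 reads in all resistant A375 libraries and 0 in the sensitive ones, and 0.385 against 0.331 CPM in SKMel28 (adjusted p = 0.737).

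Among the IGF-binding proteins, IGFBP3 rose in both lines, from 93.4 to 147 CPM in A375 (0.65 ± 0.05) and from 26.7 to 48.3 CPM in SKMel28 (0.86 ± 0.05). IGFBP5 fell in A375 from 29.1 to 0.849 CPM (-5.09 ± 0.14) and rose in SKMel28 from 2.08 to 4.14 CPM (0.99 ± 0.15). IGFBP2 rose in A375 (51.0 to 60.8 CPM, 0.25 ± 0.05) and fell in SKMel28 (90.8 to 80.3 CPM, -0.18 ± 0.05). STC1, whose product inhibits the protease that frees IGF from its binding proteins, rose in A375 and fell in SKMel28 from 28.5 to 3.79 CPM (-2.91 ± 0.09). Of 23 tested members of the list, 9 rose and 9 fell in A375 and 5 rose and 10 fell in SKMel28, with the same counts adjusted over the list alone. Among all genes tested 51.3% were called in A375 and 70.0% in SKMel28. The 15 called members in SKMel28 were no excess. The 18 called in A375 were a larger share of the list than among all genes, and this excess was not tested. The list as a whole was called in neither line (adjusted p = 0.862 and 0.499). In A375 its median was 0.16 and its mean -0.10, with camera pointing up and fry down, and in SKMel28 they were -0.20 and -0.44. The kinases and adaptors behind these receptors were not called as groups either. PI3K-AKT components had medians of 0.04 in A375 and 0.03 in SKMel28, with means of -0.07 and -0.04 (adjusted p = 0.977 and 0.826). RAS-RAF-MEK-ERK components had medians of 0.05 and 0.07, with means of -0.06 and 0.15 (adjusted p = 0.862 and 0.666), and BRAF was at 11.1 CPM in both A375 groups (adjusted p = 0.980). Of the other receptor genes fixed for description, EGFR rose in A375 (40.3 to 58.4 CPM, 0.54 ± 0.06) and fell in SKMel28 (2.53 to 1.75 CPM, -0.54 ± 0.15). EGFR lies on 7p, where the median over all genes at 2 CPM or more was -0.40 in SKMel28. In neither line did it pass the test against a fold of 1.5. In A375 AXL rose (491 to 580 CPM, 0.24 ± 0.04), NGFR fell (162 to 91.8 CPM, -0.82 ± 0.04) and MITF fell (39.6 to 31.0 CPM, -0.36 ± 0.05).

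**Figure D3:**
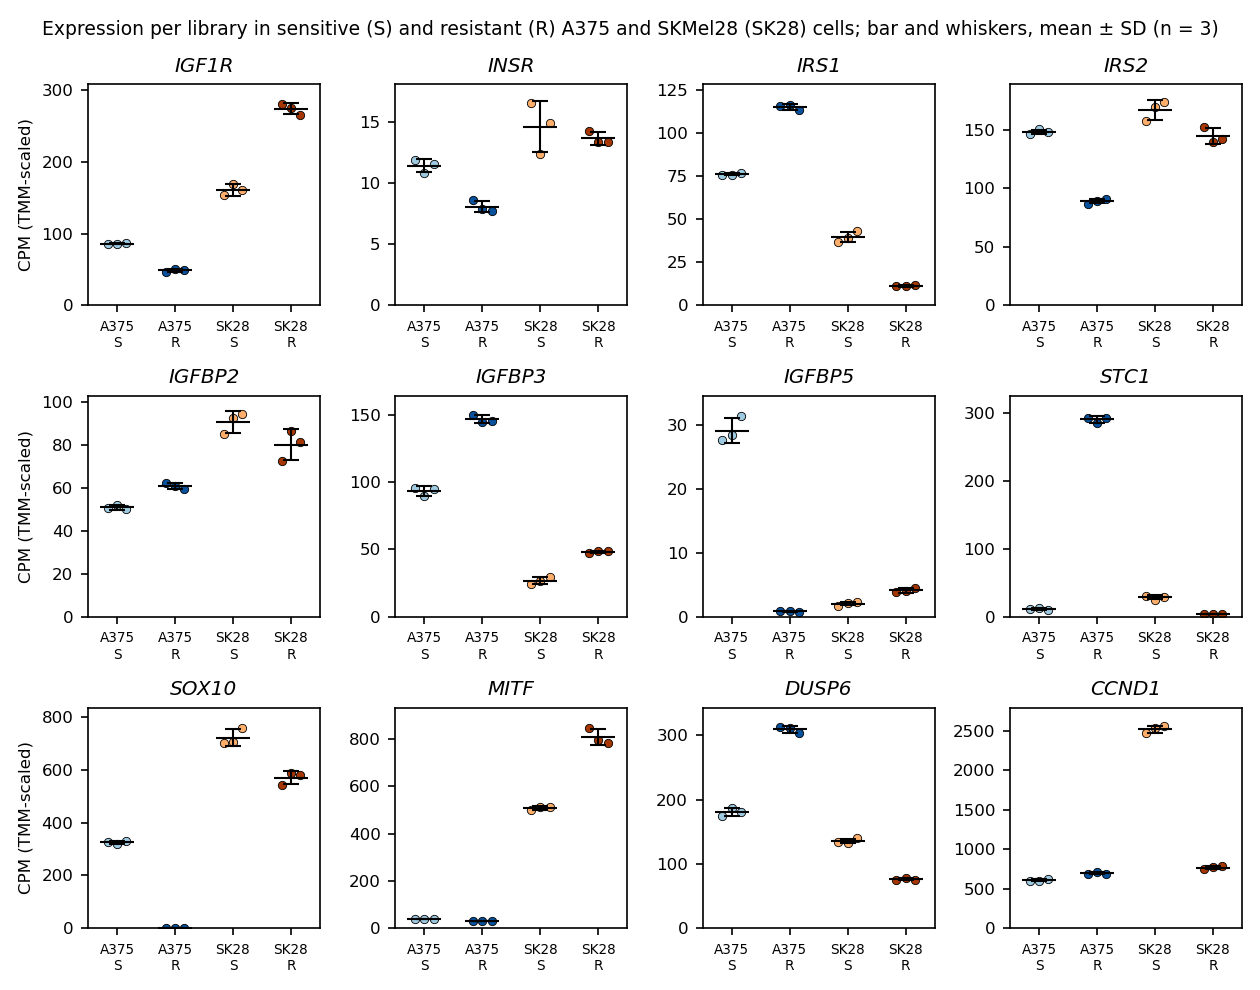
Expression (TMM-scaled CPM, y axes from 0) of 12 genes in each library of sensitive (S) and resistant (R) A375 and SKMel28 (SK28) cells; points are libraries, and bars and whiskers the mean ± SD (n = 3). IGF1R falls from 86.1 to 48.9 CPM in A375 and rises from 161 to 274 CPM in SKMel28, and SOX10 goes from 325 to 0.138 CPM in A375.

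The last comparison asked whether the lines changed alike. The change differed between A375 and SKMel28 for 9891 genes (edgeR interaction, adjusted p under 0.05). The labels name no independently derived resistant cultures of a line, so a difference between lines cannot be told apart from a difference between derivations. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson correlation of -0.03 and a Spearman correlation of -0.05. Of the genes called in both lines, 2865 went the same way and 3110 opposite ways. Independent lists of these sizes would share 1327 rises where 1341 were seen, and 1460 falls where 1524 were seen. They would share 1390 and 1394 opposite changes where 1581 and 1529 were seen. Among changes of at least 2-fold, all 4 overlaps exceeded the value for independent lists: 108 against 54 rises, 244 against 121 falls, 177 against 76 genes higher in A375 and lower in SKMel28, and 198 against 87 the other way.

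Among genes with at least 10 CPM in the higher group of each line, ranked by the smaller of the 2 changes, 5 led the rises and 5 the falls. The rises were of FHL1, a LIM-domain protein gene (2.74 in A375 and 1.23 in SKMel28), CTSK, which encodes the collagen-degrading protease cathepsin K (1.65 and 1.94), PNMA2 (1.72 and 1.53), VEPH1 (1.33 and 2.04) and PROS1, the gene of protein S (1.24 and 2.21). The falls were of FXYD3 (-4.98 and -5.12), NFATC2 (-3.05 and -2.40), the integrin gene ITGB3 (-2.99 and -2.92), CEMIP, which takes part in hyaluronan breakdown (-2.36 and -2.43), and FAM84B (-1.75 and -3.63). TFPI2 (14.5 to 130 CPM), CDCP1 (20.4 to 79.9 CPM), TMEM158 (23.8 to 266 CPM) and STC1 rose in A375 and fell in SKMel28, where TMEM158 went from 78.5 to 3.28 CPM. SERPINF1 (0.907 to 87.0 CPM in SKMel28 and 11.4 to 0.280 CPM in A375), CDH19, OLFML2A and MAL2 did the reverse. By list, 12 differed between the lines with the preset correlation. Of these, ERK output, inflammatory genes, p53 targets and cholesterol synthesis also did with an estimated correlation (adjusted p = 0.0206, 0.0206, 0.0207 and 0.0467 with an estimated correlation).

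**Figure D4:**
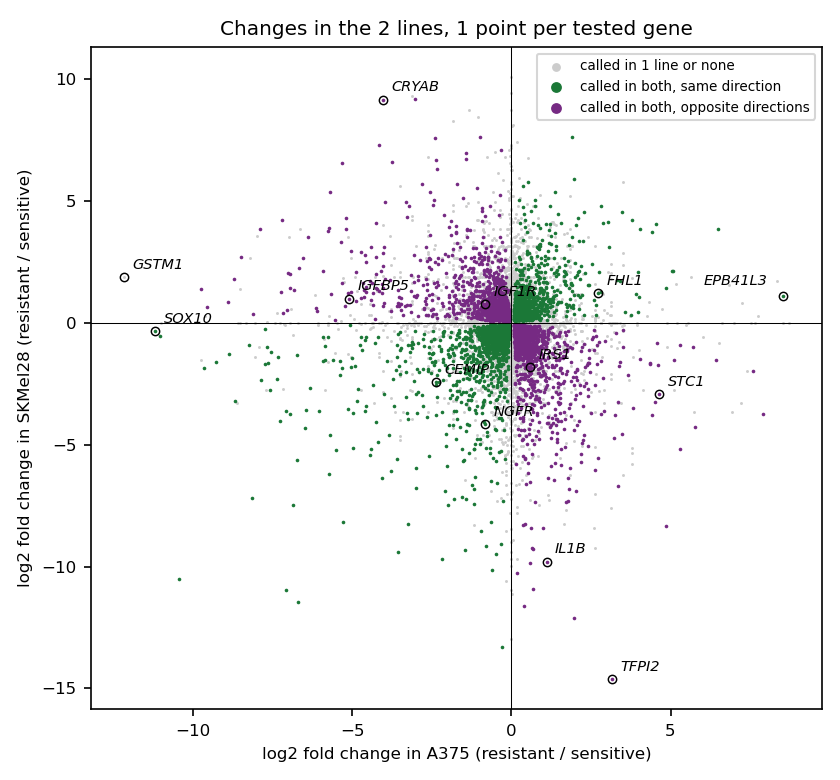
Log2 fold change (resistant against sensitive) in SKMel28 (y axis) against that in A375 (x axis), 1 point per tested gene; green marks genes called in both lines in the same direction, purple those called in opposite directions, grey the rest, and circles the labelled genes, with the fitted values of genes that had no read in a group (GSTM1, CRYAB in A375, TFPI2) resting on the prior count. The 2865 green and 3110 purple genes fill all quadrants, with IGF1R and IGFBP5 at upper left and STC1 and IRS1 at lower right.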

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

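Tests for a trend with GC content and transcript length, for the same arms in SKMel28 and for the genes around SOX10 were chosen only after the results they bear on had been seen.

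The resistant forms of A375 and SKMel28 changed by different amounts for 9891 genes by the edgeR test of the difference between lines. Other splits of the same libraries show that this count rests on the real groups, but they cannot exclude chance between cultures. A wrong split of a line removes that line's own change, and the labels do not say whether libraries came from separate cultures. Of 100 splits only the real one, 1 of 100, gave as many; the highest other split gave 6368 and kept the real groups of SKMel28, so it still held that line's change. For gene lists, the real split called 12 and the highest other split 11, again 1 of 100 with as many. Within a line, 3 against 3 libraries make 10 splits, too few for a share under 0.05: the real split called 7959 genes in A375 and the highest other 0, and in SKMel28 10854 and 0. The lists called were 10 against 5 in A375 and 8 against 7 in SKMel28. Camera with the preset correlation thus also called lists in splits where no gene was called. The number of lists in SKMel28 hardly sets the real groups apart.

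By camera on the difference, changes were on balance higher in A375 than in SKMel28 for the ERK transcriptional output (adjusted p = 2.16e-09), inflammatory genes (adjusted p = 3.76e-07) and p53 targets (adjusted p = 3.66e-04). They were lower for cholesterol synthesis (adjusted p = 0.00402), and all 4 lists were also called with an estimated correlation. Other lists were called with the preset correlation alone. Higher in A375 were immediate early genes (adjusted p = 8.74e-04, and adjusted p = 0.0567 with an estimated correlation) and the undifferentiated or invasive state (adjusted p = 0.00156, and adjusted p = 0.088 with an estimated correlation). So were lysosome and autophagy (adjusted p = 0.0116, and adjusted p = 0.164 with an estimated correlation), interferon response (adjusted p = 0.0131, and adjusted p = 0.0567 with an estimated correlation) and ribosomal proteins (adjusted p = 0.0476, and adjusted p = 0.646 with an estimated correlation). Lower in A375 were DNA replication and G1-S genes (adjusted p = 0.00592, and adjusted p = 0.0567 with an estimated correlation), mitochondrially encoded genes (adjusted p = 0.0131, and adjusted p = 0.506 with an estimated correlation) and melanocyte differentiation (adjusted p = 0.0476, and adjusted p = 0.0914 with an estimated correlation). The melanocyte and ribosomal calls of the difference were lost without single libraries, as given under the dependence on processing.

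Of 98 named genes, 85 differed between the lines in the same test, 45 with a higher and 33 with a lower log2 fold change in A375 and 7 with no read in a group. The rule took many of them for large or opposite changes, which favours a difference, and among all tested genes the share was 63.8%. In the IGF axis the difference, A375 minus SKMel28, was -1.58 for IGF1R, 2.41 for IRS1, -0.53 for IRS2, -0.40 for INSR, 0.43 for IGFBP2, -0.21 for IGFBP3, -6.09 for IGFBP5 and 7.56 for STC1. Among genes of the ERK output it was 1.90 for CCND1, 1.60 for DUSP6, 0.75 for SPRY4, 2.41 for FOSL1, 2.56 for HMGA2, 3.55 for MAFF, 5.98 for LIF and 5.45 for PLAUR. The difference was 3.69 for EGR1, 1.90 for EGR3, 1.32 for IER2 and 0.80 for JUN, all immediate early genes. It was 10.90 for IL1B and 3.16 for CXCL8, and 2.65, 1.53 and 2.40 for HLA-B, HLA-C and HLA-F. For p53 targets it was 1.34 for CDKN1A, -1.33 for FAS and 0.72 for RRM2B, and for DNA replication genes -0.52 for E2F1, -1.36 for E2F2 and -1.18 for PCNA. Among genes of cell identity it was -10.84 for SOX10, -1.02 for MITF, -6.70 for SOX5, -5.79 for FOXD3, -4.70 for NES, 0.19 for L1CAM and -11.21 for CDH19. It was 3.35 for NGFR, 2.67 for TNC, 0.47 for AXL and 1.07 for EGFR.

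Metabolic genes differed by -0.55 for DHCR7, -2.11 for INSIG1, 2.36 for PFKFB4, 1.01 for PGK1, 2.12 for VEGFA, 0.72 for COX7B and 0.49 for NDUFB8. The mitochondrial transcripts differed by -0.56 for MT-CO1, -0.24 for MT-CO2, -0.61 for MT-CO3, -0.20 for MT-CYB and -0.47 for MT-ND4. Lysosomal genes differed by 1.39 for CTSB, 0.75 for LAMP2 and 0.47 for SQSTM1, and the ribosomal protein genes by 1.01 for RPLP1, 0.80 for RPS3 and 0.73 for RPS12. Among the largest changes the difference was 7.42 for EPB41L3, 7.30 for RGS4, 6.01 for ABCA3 and for LOXL1, and 8.06 for TMEM158. On the lower side it was -9.79 for MUC5B, -12.20 for JAKMIP2, -7.59 for ANO5, -6.24 for ELFN1, -9.05 for MAL2, -11.89 for SERPINF1 and -5.79 for OLFML2A. Of the 10 genes named for moving the same way in both lines, 6 differed in size, by 1.51 for FHL1, -0.29 for CTSK, -0.71 for VEPH1, -0.98 for PROS1, -0.65 for NFATC2 and 1.88 for FAM84B. The difference was not called for PNMA2 (adjusted p = 0.190), CEMIP (adjusted p = 0.747), FXYD3 (adjusted p = 0.786) and ITGB3 (adjusted p = 0.554). For genes with no read in a group only the adjusted p of the difference is given: 0.00136 for GSTM1, 1.20e-29 for TNFAIP2, 4.49e-35 for CDCP1, 1.82e-45 for TFPI2, 3.72e-32 for PLA2G16, 2.08e-26 for SPESP1 and 1.65e-09 for CRYAB.

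Lower expression across 1p, 13q, 20p and 20q in resistant A375 cells ran along whole arms: when each arm was divided into 4 stretches of equal gene number, 16 of 16 stretches had a median log2 fold change below -0.25. The arms had been picked by the same bound on the same fold changes, which favoured a high count. It shows only that the fall was not confined to part of an arm. A trend with GC content or transcript length as the whole cause is argued against by the median of 1p, -0.53 after that trend was removed. A response to the drug or to resistance in both lines is argued against for 1p, 13q and 20p by SKMel28, where the median over their 971 genes was 0.0278 (95% -0.0178 to 0.0719). For 20q, with a median of -0.16 in SKMel28 (95% -0.35 to -0.08), such a response cannot be told apart from a change in A375 alone, because the interval holds both a small and a clear fall. Loss of copies of the arms in the cells that became resistant is a candidate explanation, which RNA alone does not show, and a regulatory change along whole arms that arose in A375 alone stays open, untested.

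The near loss of SOX10 reads in resistant A375 cells is argued not to come from a deletion of the wider region, since the 24 other tested genes within 500 kb had a median log2 fold change of 0.064 (range -1.16 to 0.64). A different cell line in place of resistant A375 is argued against by the number of genes switched between at least 10 and at most 0.1 CPM, 7 between the A375 groups against 183 between the sensitive lines (3.83%). A small deletion of SOX10 itself and silencing of the gene remain open. Growth of a SOX10-negative part of the starting culture may also have given this pattern, and acquired resistance and exposure to the drug cannot be separated in this design.

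In resistant SKMel28 cells 6 genes had no read after at least 10 CPM in sensitive ones, CDCP1, PLA2G16, RGS1, SPESP1, SPRR2D and TFPI2. A different cell line in place of resistant SKMel28 is argued against by 14 switched genes, 7.65% of the number between the sensitive lines. Over the 6 genes together, deletion of the surrounding regions cannot be told apart from silencing. Of the 12 nearest expressed neighbours 4, or 33.3% (exact 95% interval 9.92% to 65.1%), fell by at least 1 on the log2 scale. Of all expressed genes 9.33% did so, and 12 neighbours are too few to decide. The interval takes neighbours as independent, which those on the sides of the same gene may not be. The neighbours that fell by that much were LCE2A (-7.24, 340 kb away) and PRR9 (-9.26, 176 kb) on the sides of SPRR2D, TMEM158 (-4.58, 78.0 kb) by CDCP1, whose nearer neighbour EXOSC7 (46.2 kb) was at -0.11, and PLA2G4A (-1.08), 5587 kb from RGS1, whose nearer neighbour RGS2 (229 kb) was at -0.44. By PLA2G16, SPESP1 and TFPI2 the neighbours ranged from -0.52 for VPS50 (524 kb) to 0.67 for GLCE (214 kb).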

How the results depend on the processing

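Scaling by library size alone and leaving out genes of shifted chromosome arms were tests chosen only after the data had been examined. Counts of called genes, of lists and of shared genes stayed within 1.5 times the reported count in 118 of the comparisons with another setting and in all 120 that left out 1 library, and moved further in 16. No gene was called in the opposite direction under the settings that tested the genes again, and leaving out genes of shifted arms keeps the calls of the remaining genes as they are. A test against a fold of 1.5 called 1704 genes in A375 (664 higher, 1040 lower), 4035 in SKMel28 (1780 higher, 2255 lower) and 4369 for the difference. It left 363 in the same and 400 in opposite directions, and 6 members of the IGF axis in A375 where 18 were called, since it asks for larger changes. With each line fitted alone the correlation of the changes was -0.000136. It covers only genes that passed the filter in both separate fits, while the reported value covers all 15506 genes. Whether this made the difference was not tested. An estimated correlation called 3 lists in A375, 2 in SKMel28 and 4 for the difference, and fry, which does not compare a list with other genes, called 29, 30 and 31. Fry turned the direction of PI3K-AKT components (adjusted p = 0.00116) and antigen presentation (adjusted p = 0.0101) in A375 to lower, of extracellular matrix (adjusted p = 5.36e-06) and nervous system adhesion (adjusted p = 4.32e-06) in SKMel28 to lower. It turned immune cell markers in SKMel28 to higher (adjusted p = 0.0277). Camera had called none of these, and the cause was not tested.

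Leaving out 1 library at a time called 7207 to 7658 genes in A375, 10354 to 10592 in SKMel28 and 9541 to 9807 for the difference, fewer samples giving fewer calls. DESeq2 called 7918, 10780 and 9923, of which 7402, 10704 and 9636 were among those of edgeR. In A375, where 3882 genes were higher and 4077 lower, rises outnumbered falls with DESeq2 size factors (4440 and 3639), scaling by library size (4351 and 3703), DESeq2 (4357 and 3561), no filter (4398 and 3778) and without genes of shifted arms (3785 and 3027). They did so too without resistant replicate 1 (54.0% higher), 2 (54.5%) or 3 (54.9%). Leaving out shifted arms removed 1050 falls and 97 rises, which alone gives that turn. The median log2 fold change of A375 over all genes was 0 in the reported fit. It was 0.029 with DESeq2 size factors, 0.023 with library size, 0.029 by DESeq2 and 0.021 to 0.025 without a resistant replicate. In these settings the balance moved together with this median, and no other cause was tested. With no filter the median stayed at 0, and the cause of the turn there was not tested. Without genes of the shifted arms 6812 genes were called in A375 and 7775 in SKMel28. Replicate number as a block ended the calls of the ERK output (adjusted p = 0.0574) and mitochondrially encoded genes (adjusted p = 0.0533) in A375. Among differences between lines, melanocyte differentiation lost its call without any 1 of A375 sensitive 2 and 3, SKMel28 resistant 1 and SKMel28 sensitive 1, 2 and 3 (adjusted p = 0.0506 to 0.0708). Ribosomal proteins did so without any 1 of 7 libraries, A375 resistant 1, A375 sensitive 2 and 3, SKMel28 resistant 1 and 2 and SKMel28 sensitive 2 and 3 (adjusted p = 0.0536 to 0.0777). Both also lost it under the stricter filter (adjusted p = 0.0519). MLANA in A375, not called with all libraries, was called without resistant replicate 3 (adjusted p = 0.0262) or sensitive replicate 2 (adjusted p = 0.0173). At 1 CPM for 28 or more reads, genes under about 0.1 CPM rest on a few reads per library.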

Other observations

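Genes in this part, and the tests on chromosome arms and with library-size scaling, were chosen only after the data were seen, except that lists were fixed before. In resistant A375 cells 4 genes of MHC class II antigen presentation were lower. CD74, the invariant chain, went from 437 ± 4.62 to 63.7 ± 2.28 CPM (SD, n = 3; log2 fold change -2.78 ± 0.04 SE, edgeR adjusted p = 4.93e-40). HLA-DRA went from 73.3 to 2.57 CPM (-4.83), HLA-DPA1 from 57.2 to 9.99 CPM (-2.52) and their transactivator CIITA from 17.4 to 3.59 CPM (-2.27). The antigen presentation list as a whole was not called in A375: 14 of 24 rose and 9 fell, with the same counts adjusted over the list alone (median 0.22, mean -0.76, adjusted p = 0.536). Both ERBB3 and S100B also fell in A375, the receptor gene ERBB3 from 124 to 3.72 CPM (-5.06) and S100B from 10.9 to 0.0957 CPM (-6.74). In SKMel28 ERBB3 was at 133 and 124 CPM (-0.10, adjusted p = 0.0260). Of secreted matrix genes, SPARC fell from 1156 to 489 CPM in A375 (-1.24) and rose in SKMel28 (1.10). The collagenase gene MMP1 rose in A375 from 11.8 to 41.3 CPM (1.80) and fell in SKMel28 from 99.0 to 0.866 CPM (-6.82).

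In resistant SKMel28 cells MET, the receptor of hepatocyte growth factor, rose from 127 ± 3.03 to 574 ± 34.8 CPM (SD, n = 3; 2.18 ± 0.04 SE, edgeR adjusted p = 1.51e-38); in A375 it rose by 0.32. DDR2, a collagen receptor, rose as well (2.00). TYRP1, a melanin synthesis enzyme, rose from 218 to 2037 CPM (3.23) while MC1R, the melanocortin receptor gene, fell from 196 to 38.4 CPM (-2.35). The transporter genes ABCB5 (63.9 to 297 CPM, 2.22) and ABCC2 (70.1 to 175 CPM, 1.32) rose, and ABCC2 fell in A375 (-0.89). BST2, an interferon-induced membrane protein gene, fell from 110.4 to 0.576 CPM (-7.57), and TIMP1 from 362 to 81.0 CPM (-2.16). Near the IGF axis, GRB10, which encodes an adaptor that binds IGF1R and the insulin receptor, fell in SKMel28 from 109 to 35.2 CPM (-1.63). IGF2BP1, an mRNA-binding protein gene, rose there from 30.4 to 88.4 CPM (1.54). IGFBP7 fell in both lines (-0.58 in A375 and -0.93 in SKMel28), and IGFBP4 was at 566 and 523 CPM in A375 and had no read in SKMel28.

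Several chromosome arms also stood apart in SKMel28. Medians were lower on Xp (-0.70), 7p (-0.40), 5p (-0.37), 9q (-0.35), 16q (-0.34), 21q (-0.34) and 19p (-0.25), and higher on 10p (0.50), 8q (0.40), 10q (0.35), 5q (0.34), 6q (0.29) and 3q (0.28). After a trend with GC content and transcript length was removed, 19p moved to -0.06, 6q to 0.17 and 3q to 0.16, inside the 0.25 bound. The same step took 16p from 0.22 to 0.36, 17p from 0.11 to 0.26 and 1q from -0.22 to -0.26, past it, while Xp stayed at -0.71 and 7p at -0.45. No other explanation was tested for these arms.

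The list of receptor tyrosine kinases was not called in A375 (median -0.38, adjusted p = 0.0758) or SKMel28 (median -0.10, adjusted p = 0.889). The A375 result lies near the threshold. It was called lower with DESeq2 size factors (adjusted p = 0.0445), scaling by library size (adjusted p = 0.0489), no filter (adjusted p = 0.0495), the stricter filter (adjusted p = 0.0246) and without genes of shifted arms (adjusted p = 0.0499). Leaving out A375 resistant replicate 1 (adjusted p = 0.0229) or 3 (adjusted p = 0.0427) also gave the call. With an estimated correlation the list was not called (adjusted p = 0.428). Melanocyte differentiation genes were not called with all genes: in A375 10 of 34 rose and 11 fell (median 0.15, mean -0.69, adjusted p = 0.773), and in SKMel28 19 rose and 13 fell (median 0.30, adjusted p = 0.103). Without genes of shifted arms the list was called higher in SKMel28 (adjusted p = 0.0234), and with all genes and an estimated correlation it was not (adjusted p = 0.207). Adjusted over the list alone 10 rose and 12 fell in A375 and the counts in SKMel28 were the same. YAP-TEAD targets, a group linked to drug tolerance, had medians of 0.11 and 0.20 (adjusted p = 0.191 and 0.816), and drug transporters as a group -0.10 and 0.01 (adjusted p = 0.388 and 0.593). Markers of fibroblasts, keratinocytes, immune cells and endothelium, included as a check for other cells, were not called by camera in either line. In A375 they had medians of -0.30, -0.65, 0.92 and 0 (mean -0.12 for endothelium; adjusted p = 0.403, 0.130, 0.179 and 0.738), and of 8, 9, 6 and 9 tested genes 1, 3, 3 and 3 rose and 2, 5, 1 and 1 fell. Adjusted over the list alone 6 keratinocyte markers fell and 4 immune markers rose there, with the other counts the same. In SKMel28 the medians were -0.09, -1.15, -1.11 and -0.85 (mean 0.41 for fibroblasts; adjusted p = 0.796, 0.232, 0.773 and 0.226), and 3, 3, 1 and 0 rose and 2, 5, 3 and 5 fell, the same adjusted over the list alone. Fry, which does not compare a list with other genes, called fibroblast (adjusted p = 0.0314) and keratinocyte markers (adjusted p = 3.15e-06) lower and immune markers higher (adjusted p = 7.70e-06) in A375, and not endothelium (adjusted p = 0.288). In SKMel28 it called fibroblast (adjusted p = 0.00119) and immune markers (adjusted p = 0.0277) higher and keratinocyte (adjusted p = 9.75e-08) and endothelial markers (adjusted p = 2.76e-07) lower.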
